A study of Homo sapiens with 6 samples.

How the data were processed

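RNA was measured by sequencing in fractions purified from MCF7, an established human breast adenocarcinoma line first grown from a pleural effusion. There were 6 libraries, 3 from nucleoli of cells kept at 37 °C and 3 from Amyloid-bodies of cells heat shocked at 43 °C, both at 21% oxygen and pH 7.4, per the labels' protocols. Amyloid-bodies are solid-like nuclear condensates that form in stressed cells. The titles and the series' design text give 60 min of heat shock, whereas the growth protocol gives 2 h, and this conflict could not be settled from the labels. Cells were broken by sonication, the fractions were pelleted through sucrose, RNA was extracted with Trizol and libraries were made with a KAPA stranded mRNA kit, per the labels' protocols. The treatment and the purified compartment changed together, so the comparison does not separate them, and whole-cell RNA was not analysed here. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

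The submitters' processing notes name bcl2fastq, STAR 2.5.0, Cufflinks 2.2.1, Cuffnorm and the build GRCh38, with no role or order. The annotation release is not given in the sources used here. The deposited table holds FPKM values, fragment counts scaled to transcript length and library size, for 98 entries, each with a Cufflinks identifier, a gene name, a locus and 3 lines. Each line of the authors' table has 1 nucleolar value, 1 Amyloid-body value and their ratio, and all 294 of the deposited ratios equalled the quotient of the FPKM values within a relative tolerance of 1e-06. The lines carry no replicate numbers, so values were assigned to a group and not to a numbered library, and a line's place among the 3 is called its row. The lowest Amyloid-body value was 3.16 FPKM and the lowest ratio was 3.06, so the table appears to be a list of entries selected for values above 3 on both measures. This rule is inferred from the minima, as none is given in the sources used here. If it holds, every entry is higher in Amyloid-bodies by selection. Genes that were lower or did not differ are not analysed here. The table's total is that of 98 entries and not a sequencing depth. Depth is unknown, since no counts are given and Cufflinks estimates abundance with a likelihood model, so no counting interval was computed.

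Among the nucleolar values, 25 were exactly 0.1 FPKM, in 17 entries, and none of the Amyloid-body values was. The origin of this value is not given in the sources used here, and the lowest other nucleolar value was 0.0788 FPKM. In 3 entries all 3 nucleolar values were 0.1, and for these no fold is given. The authors' deposited table also has an average ratio per entry. It equalled the mean of the entry's own 3 ratios in 76 entries, within a relative tolerance of 1e-09. In the last 22 entries, from place 77 of the table on, it equalled the mean of the ratios found 2 lines further down. Own ratios were therefore used throughout.

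Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a mean-variance trend in the empirical Bayes step, a two-sided test and Benjamini-Hochberg adjustment at 0.05. Differences are on the log2(FPKM + 1) scale, which understates the change of low entries. A filter of at least 1 FPKM in 3 or more libraries removed 0 entries. No replicate block was used in the main test. Applied to simulated values for 98 entries with 49 changed, over 100 simulations, the test recovered 75.6% of entries changed by 1 on the log2 scale and 95.3% of those changed by 2, and 2.79% of its calls were false. The simulated values were drawn independently and included unchanged entries, whereas every ratio in the table is above 3. The share of false calls therefore does not carry over to the listed entries.

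The test, the alternatives, 20 gene lists and the rule for named genes were fixed before the data were examined. The rule took the 12 entries with the largest positive and the 12 with the largest negative difference among those past the test without overlap between groups, up to 4 members of each list with the smallest adjusted p, and the 5 entries with the highest mean FPKM, which gave 26 entries. No entry was lower, so the negative part named none. The lists were HSF1 chaperones, other proteotoxic stress genes, immediate early genes, endoplasmic reticulum unfolded protein response, cytosolic ribosomal proteins, translation factors, mitochondrially encoded transcripts, nucleolar proteins, small nucleolar and nuclear RNAs with 7SL and 7SK, their host genes, nuclear long noncoding RNAs, ribosomal RNA, histones, proliferation, estrogen response, zinc finger factors, interferon and inflammation, other cell types, keratins and cytoskeleton, and splicing factors. Lists with 5 or more entries were compared with the other listed entries by camera, with a preset correlation of 0.01 and with an estimated one, and tested on their own by fry, each adjusted over 3 lists. Camera compares moderated t statistics, in which a difference is divided by its standard error, and not the differences themselves. Since the table holds part of the transcriptome, no enrichment against the genome was computed.

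The rows were checked for pairing. Deviations from the group means in the same row of both groups correlated across entries at 0.164, 0.402 and 0.381, above the highest correlation with another row in each case (0.0959, -0.0870 and -0.0383). The order of values was not random over rows, as 10000 permutations of the values within entries gave a permutation p of 0.0025 for nucleoli and 0.0010 for Amyloid-bodies. By the rule that every pair must exceed 0.1, the rows were taken to pair the libraries. This pairing comes from the values and not from the labels, and the blocked result is printed where it changes a call.

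Alternatives were pseudocounts of 0.1 and 0.01, no filter, a filter of 5 FPKM, median centring, quantile normalization, the variance prior without trend or with robust estimation, an added difference of at least 1, leaving out each library, and, chosen after seeing the data, a block by row, exact 0.1 values set to 0 or left out, and 1 entry per gene name. A count test could not be run on FPKM. Gene positions and types came from GENCODE release 29 on GRCh38. Gene symbols were counted once for each entry that names them, which gave 104. Of these, 102 were found, 3 of them by an older symbol, and 98 overlapped the entry's locus. Loci are printed 1-based. In 60 entries the deposited locus start lay 1 base before an annotated gene start, so 1 was added to all starts. Positions of listed genes were compared with random gene sets in Python 3.11.15 with NumPy 2.4.6 and pandas 2.3.3. Figures were drawn with matplotlib 3.10.9.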

Results

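RNA of nucleoli from unstressed MCF7 cells was compared with RNA of Amyloid-bodies from heat-shocked cells, with 3 libraries in each group, to ask which messages the stress-formed condensates hold. The deposited list held 98 entries under 94 gene names. Summed over these entries, the 3 rows of nucleolar values came to 669, 611 and 869 FPKM and the 3 rows of Amyloid-body values to 4977, 5374 and 6797 FPKM. The 10 highest entries took 65.1% to 70.1% of the sum in each row. Across entries, log2(FPKM + 1) values correlated at a Pearson r of 0.901 to 0.970 within groups and 0.720 to 0.830 between groups, where entries are not independent replicates. The first principal component, with 94.2% of the variance, separated the groups. Since every ratio in the table is above 3, the higher sums and this separation were fixed by the entries listed. They are not independent evidence that the libraries differ.

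Some heat shock chaperone transcripts and some small RNAs were among the entries with the largest differences. By size of difference, the entries of HSPA6, HSPA1A and DNAJB1 ranked 1, 5 and 11. The small RNA entries RNA5S9, RN7SL472P, RNU6-42P, U1 and RN7SKP49 ranked 2, 6, 8, 10 and 12. Further down, the chaperones HSPA4L and HSPB1 ranked 72 and 82, and the small RNA RMRP ranked 57. The entry of HSPA6, a strictly stress-inducible HSP70, was at 0.597 ± 0.650 FPKM in nucleoli and 308 ± 69.9 FPKM in Amyloid-bodies (SD, n = 3 each). HSPA1A, the main inducible HSP70, was at 0.533 ± 0.152 and 37.1 ± 5.68 FPKM, and DNAJB1, an HSP40 co-chaperone, was at 81.7 ± 18.0 and 834 ± 142 FPKM (SD, n = 3 each). IER5, an immediate early gene product that acts on HSF1, was at 12.4 ± 1.38 and 388 ± 54.4 FPKM, and the long noncoding RNA AC108134.2 was at 5.97 ± 0.309 and 221 ± 50.0 FPKM (SD, n = 3 each). JUN, a subunit of the AP-1 transcription factor, was at 8.44 ± 2.74 and 88.7 ± 12.7 FPKM (SD, n = 3 each).

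With limma and Benjamini-Hochberg adjustment, 98 of the 98 entries were higher in Amyloid-bodies and 0 were lower, with a largest adjusted p of 0.00877, and 98 were also higher at an unadjusted p under 0.05. Every ratio in the table is above 3, and if the list was selected on this, a rule inferred from its minima and stated in no source used here, the direction was fixed in advance and is not independent evidence of a rise. Differences ran from 1.27 (ST13P6) to 7.65 (HSPA6) on the log2(FPKM + 1) scale, with a median of 2.28. Centring each library on its median moved the median difference to -0.34 and left 33 entries past the test, 10 higher and 23 lower. Quantile normalization moved it to -0.20 and left 35, 11 higher and 24 lower. Either scaling removes the rise that the listed entries share and leaves the median difference below 0. An entry close to the listed median, such as HBA1 or COL1A1, can thus turn negative. Directions below are those of the deposited FPKM unless stated.

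**Figure D1:**
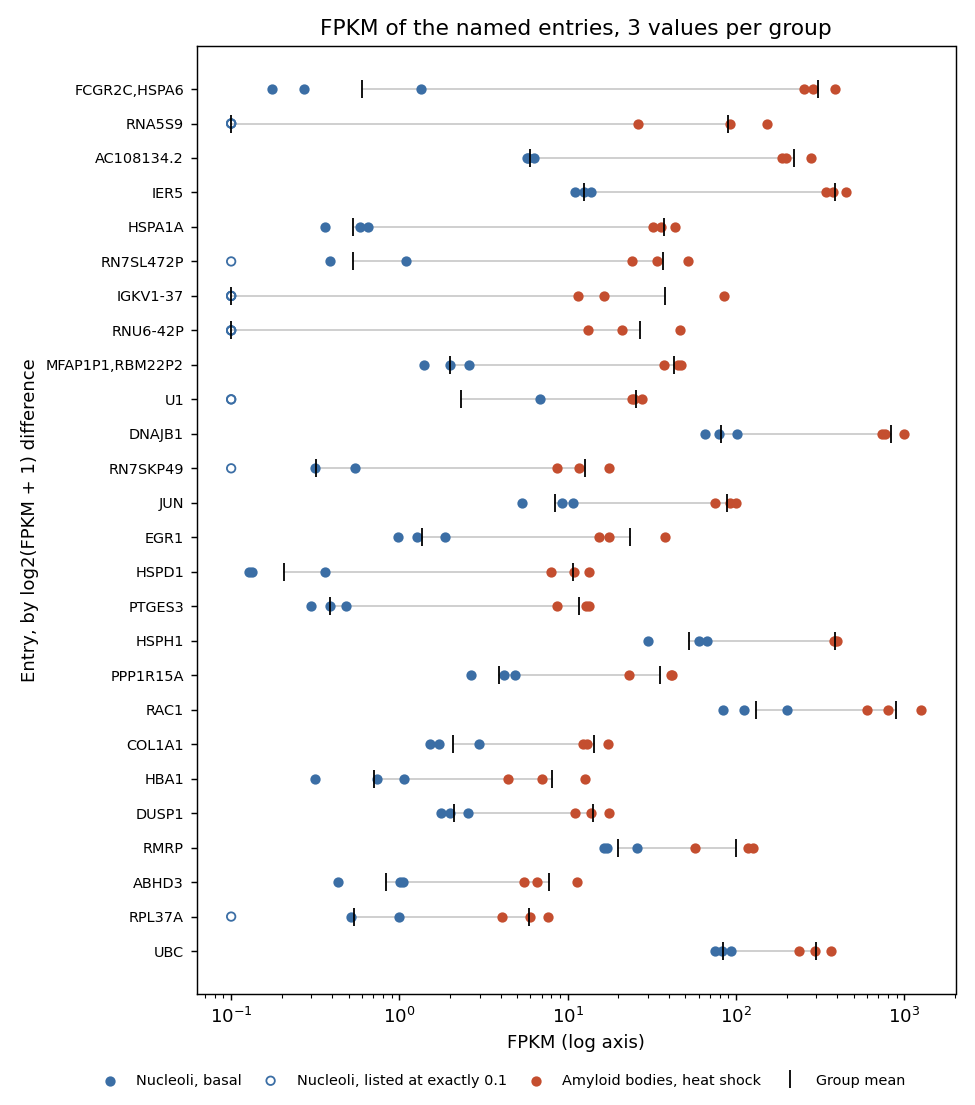
FPKM (log axis) of the 26 named entries, with 1 point per value, 3 per group, blue for basal nucleoli and red for heat-shock Amyloid-bodies, open points for nucleolar values of exactly 0.1 and a black tick for each group mean. Entries are ordered by their log2(FPKM + 1) difference, which is largest for HSPA6 (7.65) and, of the named entries, smallest for UBC (1.81), at the bottom. On the plotted FPKM axis the group means of RNA5S9 lie further apart than those of HSPA6. UBC turned negative under median centring and quantile normalization.

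The HSF1 chaperone list, the targets of the main heat shock transcription factor, had 13 entries under 12 gene names. All 13 were higher in Amyloid-bodies, also when adjusted over the list alone, which adds no evidence, since all 98 listed entries passed. Their median difference was 3.04, against 2.26 for the other listed entries. HSPA6 differed by 7.65 ± 0.315 (SE), with a limma Benjamini-Hochberg adjusted p of 7.42e-07. HSPA1A differed by 4.63, DNAJB1 by 3.34, HSPH1, an HSP110 nucleotide exchange factor, by 2.95, and PTGES3, the HSP90 co-chaperone p23, by 3.16. HSPD1, the mitochondrial HSP60, went from 0.207 ± 0.132 to 10.8 ± 2.72 FPKM (SD, n = 3 each), a difference of 3.27, and its nucleolar mean was 0.131 without the highest value. The other entries of the list were BAG3 in 2 entries, DNAJA4, HSPA4L, HSPB1, DNAJB4 merged with GIPC2, and HSPE1-MOB4 merged with AC020550.1. Against the other listed entries, camera placed the list's t statistics higher, with a Benjamini-Hochberg adjusted p of 0.0485 at the preset correlation. The call was lost with an estimated correlation (adjusted p = 0.185) and with the rows as a block (adjusted p = 0.212), and also without row 1 of the nucleoli (adjusted p = 0.0547), row 1 of the Amyloid-bodies (adjusted p = 0.165) or row 3 of the Amyloid-bodies (adjusted p = 0.0855). It was lost as well with pseudocounts of 0.1 and 0.01 (camera adjusted p = 0.0639 and 0.0707), quantile normalization (0.0554) and 1 entry per gene name (0.0782). It was kept under median centring (camera adjusted p = 0.00871), without a variance trend (0.0212), with the 5 FPKM filter (0.0193) and with exact 0.1 values set to 0 (0.0436) or left out (0.0433). The fry test of the list on its own (adjusted p = 2.34e-06) adds no evidence, since every ratio in the table is above 3. Most calls in the list were lost under scaling. Under median centring 3 of the 13 entries were higher and 1, HSPB1, lower past the test, and under quantile normalization 4 were higher and 1, a BAG3 entry, lower.

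The mean log2(FPKM + 1) of the HSF1 chaperone entries was 2.28 ± 0.0740 in nucleoli and 5.57 ± 0.0946 in Amyloid-bodies (SD, n = 3 each). The difference was 3.29, and since every ratio in the table is above 3, a difference beyond the spread in either group was fixed by the entries listed. The exact two-sided permutation p was 0.1, the smallest that 20 assignments allow. Centring on the median reduced the difference to 0.66 and quantile normalization to 0.64.

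The HSPA6 entry is on GRCh38 chromosome 1 at 161505430 to 161608528, a locus that the table gives to FCGR2C as well, and its nucleolar mean rests on 1 value of 1.35 FPKM beside 0.269 and 0.176, and is 0.222 without it. The HSPA1A entry lies on an alternate contig at 3071292 to 3073774. The gene's copy on the main chromosomes and the nearly identical HSPA1B can share its reads, so its FPKM may be only part of the gene's. DNAJB1 spans 14514770 to 14529770 on chromosome 19, HSPH1 31134974 to 31162388 on chromosome 13, and HSPD1 197486581 to 197516737 on chromosome 2, in GENCODE. IER5 spans 181088712 to 181092899 on chromosome 1, JUN 58780788 to 58784327 on chromosome 1, and AC108134.2, annotated as a long intergenic noncoding RNA, 3156736 to 3157483 on chromosome 16.

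**Figure D2:**
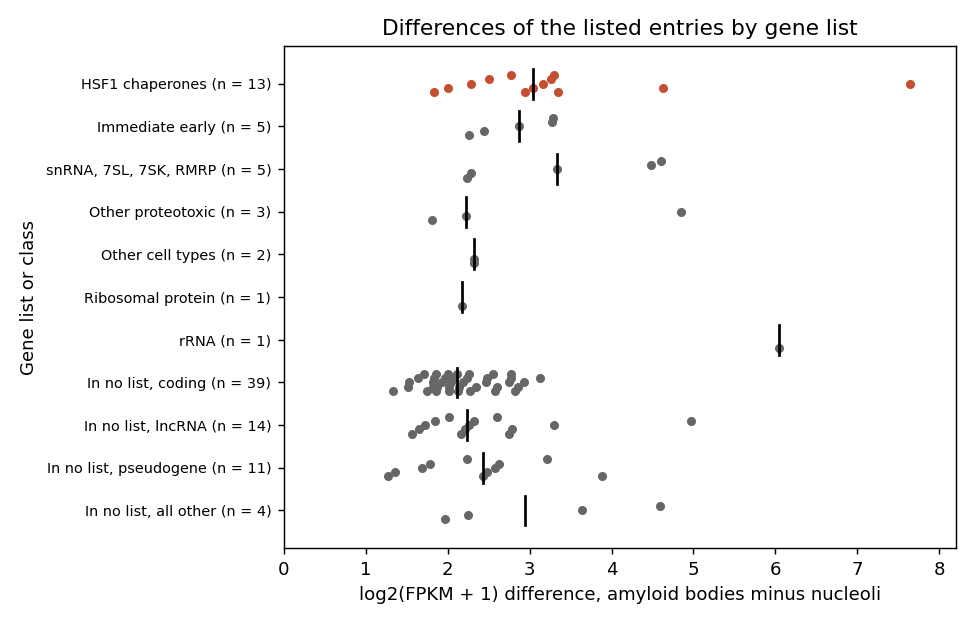
Difference in log2(FPKM + 1), Amyloid-bodies minus nucleoli, for each of the 98 entries (points) by gene list or, for entries in no list, by gene class, with a black line at each median. The 13 HSF1 chaperone entries (red) have a median of 3.04, and all points lie above 0 because every ratio in the table is above 3; under median centring 4 of the 13 fell below 0.

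Immediate early genes had 5 entries, and all 5 were higher in Amyloid-bodies, as were all 98, also when adjusted over the list alone. JUN differed by 3.28, EGR1, a zinc finger transcription factor, by 3.27, PPP1R15A, a phosphatase subunit that reverses eIF2α phosphorylation, by 2.87, and DUSP1, a MAP kinase phosphatase, by 2.26, and FOS was the other entry. Under median centring and under quantile normalization 0 of the 5 passed the test and DUSP1 and FOS turned negative; JUN, for example, differed by 0.66 and 0.65 (limma Benjamini-Hochberg adjusted p = 0.103 and 0.133). The list's median of 2.87 and its mean of 2.83 lay above those of the other entries (2.27 and 2.56). Camera, which compares t statistics and not differences, placed the list lower, with a Benjamini-Hochberg adjusted p of 0.974. Other proteotoxic stress genes had 3 entries, all higher. IER5 differed by 4.85, ABHD3, a phospholipase, by 2.22, and UBC, a polyubiquitin gene at 83.6 ± 9.40 and 299 ± 65.2 FPKM (SD, n = 3 each), by 1.81. ABHD3 and UBC turned negative under both scalings, UBC past the test.

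The list of small nuclear RNAs, 7SL, 7SK and RMRP, matched by name, took 5 entries, all higher, as were all 98, also when adjusted over the list alone. By their symbols, all but RMRP are pseudogene copies of 7SL, 7SK, U6 or U1 and not the functional genes. GENCODE types these copies as misc_RNA or snRNA, so they were not counted among the pseudogene entries. Of the 5 entries, 2 stayed higher past the test under median centring and under quantile normalization. RMRP, the RNA of the mitochondrial RNA processing ribonuclease, was at 19.8 ± 5.25 and 100.4 ± 37.6 FPKM (SD, n = 3 each), a difference of 2.23 that turned negative under both scalings, past the test under quantile normalization. RN7SL472P differed by 4.61 and RN7SKP49 by 3.33. RNU6-42P was listed at 0.1 FPKM in all 3 nucleolar values and was at 27.0 ± 17.4 FPKM in Amyloid-bodies (SD, n = 3), or 17.2 without the highest value, and RNU1-106P was the other entry. The list's median was 3.33, against 2.27 for the other entries. On t statistics camera again placed the list lower, with a Benjamini-Hochberg adjusted p of 0.671. The single ribosomal RNA entry, RNA5S9, was listed at 0.1 FPKM in nucleoli and was at 90.1 ± 63.4 FPKM in Amyloid-bodies (SD, n = 3), or 58.7 without the highest value. The entry named U1, also a small nuclear RNA but missed by the list's name patterns, differed by 3.64, with 2 of its nucleolar values at 0.1, and was not past the test under either scaling. Apart from RMRP, these RNAs come from multicopy families, so reads can be split among copies. For all of them, the library kit selects polyadenylated RNA. The small RNA class, with 8 entries, also takes in RNA5S9, U1 and Y_RNA. Its median difference was 3.49, against 3.04 for the HSF1 chaperone list. Under median centring the 2 medians were 0.86 and 0.42, and under quantile normalization 1.01 and 0.44. Several entries of the class had nucleolar values of exactly 0.1.

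RPL37A was the only entry for cytosolic ribosomal proteins, at 0.536 ± 0.447 and 5.87 ± 1.76 FPKM (SD, n = 3 each), with a nucleolar mean of 0.307 without the highest value. Markers of other cell types had 2 entries, the fibroblast collagen COL1A1 at 2.07 ± 0.786 and 14.2 ± 2.79 FPKM and the erythroid globin HBA1, nearly identical to HBA2, at 0.704 ± 0.373 and 8.02 ± 4.22 FPKM (SD, n = 3 each). RPL37A differed by 2.17, COL1A1 by 2.33 and HBA1 by 2.32, and all 3 turned negative under median centring and quantile normalization. RAC1, a Rho family GTPase, had the highest mean of the listed entries, at 132 ± 61.0 and 886 ± 334 FPKM (SD, n = 3 each), a difference of 2.77 that turned negative under quantile normalization. IGKV1-37, an immunoglobulin gene segment on an alternate contig, was listed at 0.1 FPKM in nucleoli and was at 37.6 ± 41.0 FPKM in Amyloid-bodies (SD, n = 3), a mean that falls to 13.9 FPKM without its value of 84.8. The pseudogene entry MFAP1P1 with RBM22P2 differed by 3.89.

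The other 13 lists, which hold fixed names or name patterns and not every gene of their kind, had 0 entries in the table. These were the endoplasmic reticulum unfolded protein response, translation factors, mitochondrially encoded transcripts, nucleolar proteins, host genes of small nucleolar RNAs, nuclear long noncoding RNAs, histones, proliferation, estrogen response, zinc finger factors, interferon and inflammation, keratins and cytoskeleton, and splicing factors. The zinc finger list was matched by name patterns alone and does not take EGR1. Because the table holds part of the transcriptome, the absence of a gene from it gives no direction, and no test was made of these lists.

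On chromosome 2, HSPD1, HSPE1-MOB4, the processed pseudogene AC020550.1 and RFTN2 lay between 197486581 and 197676045. HSPD1 and RFTN2 are on the minus strand and HSPE1-MOB4 and AC020550.1 on the plus strand. RFTN2, which encodes a lipid raft protein, was named here for its position after its values were seen. Its 2 entries were at 0.224 ± 0.0893 and 0.443 ± 0.431 FPKM in nucleoli and at 5.77 ± 0.686 and 5.15 ± 1.35 FPKM in Amyloid-bodies (SD, n = 3 each). The nucleolar mean of 0.443 includes a value of exactly 0.1 and is 0.201 without its highest value. The difference turned negative in both entries under median centring (-0.16 and -0.52) and in the latter under quantile normalization (-0.12).

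**Figure D3:**
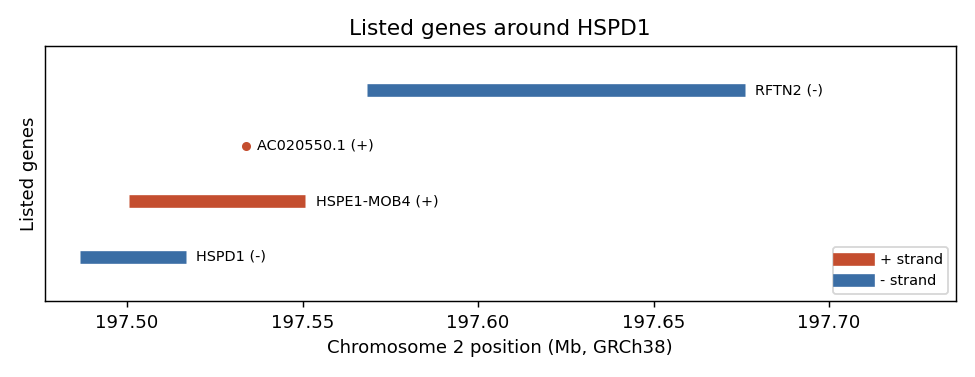
Listed genes on chromosome 2 around HSPD1, drawn to scale by GENCODE start and end (x axis, Mb, GRCh38), coloured by strand; other genes of the region are not drawn. HSPD1 and HSPE1-MOB4 overlap on opposite strands, and RFTN2 ends at 197676045.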

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

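The blocks by row, the treatments of exact 0.1 values and the single entry per gene name were chosen after seeing the data, and the other alternatives were planned. The count of 98 entries, all higher, stayed at 98 with both pseudocounts, no filter, both variance priors, the added difference of at least 1, the row block, 0.1 values set to 0 and each library left out, and was all of the fewer entries tested with the 5 FPKM filter (74), without entries at 0.1 (81) and with 1 entry per gene name (94). The filter of 1 FPKM removed no entry, so running without it tests nothing, and robust estimation does not enter camera. Median centring left 33 and quantile normalization 35 entries. By construction both remove the shared rise of a list in which every ratio is above 3, and the median difference was then -0.34 and -0.20. Reversals close to these medians, such as those of HBA1 and COL1A1 under median centring, do not set an entry apart from the list. Under median centring the named entries UBC (-0.82), HBA1 (-0.30), COL1A1 (-0.30), ABHD3 (-0.40), RPL37A (-0.46), DUSP1 (-0.36) and RMRP (-0.39) reversed, and under quantile normalization UBC (-1.28), HBA1 (-0.074), COL1A1 (-0.28), ABHD3 (-0.24), RPL37A (-0.21), DUSP1 (-0.34), RAC1 (-0.13) and RMRP (-0.90) did. Of these reversals, UBC under both scalings and RMRP under quantile normalization passed the test. A further 9 named entries under median centring (JUN, U1, RN7SKP49, PTGES3, HSPH1, PPP1R15A, HSPD1, EGR1 and RAC1) and 7 under quantile normalization (JUN, U1, RN7SKP49, HSPH1, PPP1R15A, DNAJB1 and EGR1) stayed positive but no longer passed.

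The number of lists past camera went from 1 to 0 with an estimated correlation, pseudocounts of 0.1 and 0.01, quantile normalization, the row block and 1 entry per gene name, and ranged from 0 to 1 without single libraries. The camera p of the HSF1 chaperones, 0.0162 unadjusted, was then 0.0618, 0.0213, 0.0236, 0.0185, 0.0706 and 0.0261 in the same order, and 0.00588 to 0.0551 without single libraries. The row block changed no other call. The immediate early genes, with a camera value of 0.974, changed side without passing the test with pseudocounts of 0.1 (0.717) and 0.01 (0.621), median centring (0.227), quantile normalization (0.269), no variance trend (0.891), the row block (0.643) and 1 entry per gene name (0.980), and also without row 1 (0.769) or 2 (0.954) of the nucleoli and row 1 (0.748) or 2 (0.715) of the Amyloid-bodies, in a range of 0.396 to 0.992 over the 6 libraries left out. The small RNA list changed side under median centring (0.0428, adjusted 0.0642) and quantile normalization (0.0837) and without row 1 of the Amyloid-bodies (0.774), in a range of 0.346 to 0.787 over the 6 libraries left out. The cause of these changes of side was not tested. The HSF1 chaperone score difference of 3.29 was 4.02 and 4.17 with pseudocounts of 0.1 and 0.01, 3.41 with the 5 FPKM filter, 0.66 with median centring and 0.64 with quantile normalization, and 3.24 to 3.33 without single libraries. A fit with the labels' replicate numbers as a block was not run, because the table's lines carry none, and no count test was run on FPKM. Depth is unknown, so what it limits was not measured.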

Other observations

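Tests of gene positions and of transcript start groups were chosen after the results were seen, and the count over splits of the libraries was planned. Outside the fixed lists, the table held 14 long noncoding RNA entries, with a median difference of 2.24, and 11 pseudogene entries, with a median of 2.43. All were higher in the deposited FPKM, as every entry of the table is. Under median centring 10 of the 14 and 9 of the 11 lay below 0, and under quantile normalization 8 and 6 did. Of the 63 coding entries, 43 and 44 lay below 0 under the same scalings, so this was not particular to the 2 classes. Past the limma test, 3 of the 14 and 4 of the 11 were lower and 1 of each higher under either scaling. Several pseudogenes derive from chaperone or keratin genes, and were picked out after their values were seen. HSP90AA2P went from 6.01 ± 0.547 to 21.6 ± 0.693 FPKM, ST13P6 from 0.988 ± 0.183 to 3.78 ± 0.394, KRT8P3 from 7.40 ± 2.42 to 37.7 ± 5.66 and KRT8P10 from 0.712 ± 0.342 to 4.82 ± 0.736 FPKM (SD, n = 3 each). All 4 were negative under median centring (-0.94, -1.36, -0.39 and -0.85 in that order) and quantile normalization (-1.01, -1.02, -0.46 and -0.63), and all but KRT8P3 were then lower past the limma test. Their reads can be shared with the parent genes. Antisense to ABHD3, AC106037.2 had 3 entries, at 1.60, 1.01 and 1.19 FPKM in nucleoli and 16.7, 11.3 and 9.52 FPKM in Amyloid-bodies. Whether the values were counted by strand is not given in the sources used here.

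Listed genes often lay near each other: of 87 genes placed on the main chromosomes, 22 had another listed gene within 250 kb, in 9 groups. In 1000 random sets matched on gene type and on coding gene density, the median was 4 and the highest 13, so chance positions gave too few (permutation p = 0.001, the smallest 1000 sets can give); the random genes were not matched on expression, which stays open. Keeping 1 gene per Cuffnorm locus left 14, above the 95th percentile of 7 and the highest of 12, so entries cut from one locus do not account for all of it. Loci counted as separate can nearly abut, as that of ABHD3 ends at 21704805 and that of MIB1 starts at 21704957. Links between such neighbouring loci were not tested. A candidate explanation is proximity to heat-induced chaperone genes. BAZ2A, IDH3A, RFTN2 and TIMELESS, 4 genes outside the HSF1 list, lay within 250 kb of a listed HSF1 chaperone (95th percentile 1, highest 4, permutation p = 0.002). BAZ2A and IDH3A share a Cuffnorm locus with that chaperone, and without such genes 2 were left, RFTN2 and TIMELESS (95th percentile 1, highest 3, permutation p = 0.016). The random sets for both counts were drawn without the clustering that the listed genes show in general. Neither p can therefore tell proximity to chaperones from that clustering, and 6 of the 9 groups, with 14 genes, hold no gene of the HSF1 list.

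Several coding entries bear names of genes abundant in most cells and yet had low nucleolar FPKM, among them RPL37A (0.536, or 0.307 without its highest value), HSPD1 (0.207, or 0.131), PTGES3 (0.389) and HSPB1 (0.531). Such an entry may be a partial or separate transcript model of the gene, or mature mRNA may be depleted from nucleoli. The apparent selection of the table for ratios above 3 can also favour entries with low nucleolar values, which was not tested. Among entries naming 1 gene, the 21 with 1 start group where GENCODE has 5 or more starts had a median nucleolar value of 1.44 FPKM, against 2.64 for the 36 other coding entries, a factor of 1.84 (95% bootstrap interval 0.496 to 6.68, permutation p = 0.307). Including entries that name 2 genes, whose starts can be those of either gene, the factor was 2.07 (permutation p = 0.144). The interval was added after both factors were seen, since these lay on either side of the bound of 2 set for this test. It covers both no difference and one above 2, so the transcript model and the depletion cannot be told apart.

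The 6 libraries can be split into 3 and 3 in 10 ways. The real split gave 98 entries past the limma test and the highest of the others 0, and 1 split of 10 is too large a share to fall under 0.05. Every ratio in the table is above 3 under the real grouping, so this contrast was fixed by the entries listed and tests nothing.

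In the authors' deposited table the average ratio of HSPA4L is 20.1, whereas its own 3 ratios average 5.43, and for KRT8P3 the values are 44.7 and 5.41. For RNU1-106P they are 3.70 and 43.7, but 2 of its 3 nucleolar values are exactly 0.1 and the other is 4.53, so neither is a firm ratio. Of the 12 entries with the highest mean ratio, 9 had a nucleolar value of exactly 0.1, and 8 were also among the 12 with the largest log2(FPKM + 1) difference.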
